A study of Homo sapiens with 6 samples.

How the data were processed

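RNA from LS174T cells was measured on 6 one-colour oligonucleotide arrays of 54675 probe sets, 3 from ET cells (ERT2 alone) and 3 from NET cells (NTCF joined to ERT2). Groups and replicate numbers were taken from the sample titles. The labels describe the samples as biological replicates without naming separate cultures or passages, so p-values measure the spread between these samples, part of which may be technical. Per the labels' protocols, both groups received 1 µM 4-hydroxytamoxifen for 36 h, and no untreated cells were analysed here. Per the same protocols, replicate 1 of each group was labelled by a one-cycle IVT kit and replicates 2 and 3 by SPIA cDNA amplification. The group is therefore not confounded with the kit.

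The authors deposited 1 table of log2 values per probe set and array. Per the submitters' processing notes the values were made with RMA, which corrects background, quantile-normalises and summarises the probes of a probe set. The RMA version is not given in the sources used here, nor is whether the 6 arrays were processed together. The log2 scale was inferred from the values, which ran from 2.61 to 14.98 with no negative value. Array medians of 6.14 to 6.21 place the arrays on 1 scale, but their quantiles were not identical. Scanner intensities were not used here, so saturation and background could not be measured directly, and small differences of dim probe sets are compressed. For arrays, the number of replicates limits the precision.

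Probe sets were named through the platform annotation, with 41091 having 1 gene symbol, 1801 several and 11721 none, besides 62 controls. Gene numbers matched 41037 of the single-symbol probe sets to a current gene table, and 0 symbols needed updating. Each of 19775 genes was represented by the single-symbol probe set with the highest mean over the 6 arrays, and no filter on level was applied. Probe sets with several symbols or none were tested separately and are not named. Of the 2971 genes that passed, 1856 had several probe sets, and 5 had another probe set that changed in the opposite direction. Some genes of the lists, and 1 gene meant to be named in every case, are not reported here.

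Differential expression was tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) on the log2 values, with group and labelling kit as terms. The fit left 3 residual degrees of freedom and estimated 4.91 prior degrees of freedom for the variance. Differences are NET minus ET, SE is the moderated standard error, and p-values are two-sided and adjusted by Benjamini-Hochberg over all genes, with 0.05 as the threshold. The SD of a group's values includes the kit difference, whereas the SE does not.

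A total of 22 gene lists was written before the data were examined: Wnt targets, intestinal stem cell, absorptive, goblet, enteroendocrine and Paneth cell genes, DNA replication, mitosis, ribosome biogenesis, p53 targets with CDK inhibitors, BMP and TGF-beta, Notch, Wnt pathway components, mesenchymal, blood and endothelial, epithelial, interferon, endoplasmic reticulum stress, cholesterol synthesis, glycolysis and hypoxia, oestrogen response, and ephrins. They held 586 entries, 544 of them measured, from 523 distinct genes. Each list was tested with camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg over the lists. Estimated correlation and fry were alternatives. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. With an estimated correlation none of the 12 lists that passed camera kept its call.

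The naming rule was also fixed before the data were examined. It took the 12 largest rises and 12 largest falls among passing genes whose 3 NET values all lay beyond the 3 ET values relative to the kit's ET mean, which makes all 3 same-numbered pairs agree in sign, up to 4 members of each list with the smallest adjusted p, and a short set of genes named in every case, 14 of which were measured. The report states which further genes were named after their values were seen.

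Whether replicate numbers pair the samples was checked before the fits were compared, as the labels do not state it. Deviations from the group means correlated across genes at 0.79, 0.57 and 0.70 for same-numbered ET and NET arrays, and each array correlated best with the array of its own number. Part of this is the labelling kit. Within SPIA a single comparison is possible, and the difference of replicate 2 minus replicate 3 correlated across genes at 0.51 between ET and NET. The numbers therefore appear to pair the arrays, but the main fit models the kit and not the replicate number. Values from the fit with replicate number as a block are given where they change a call or a count by over 1.5 times. That block contains the kit.

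RNA quality was compared through control probe sets. The 3′ minus 5′ difference of actin was higher with IVT (2.57 and 2.37) than with SPIA (0.17 to 0.75). NET minus ET differences were −0.29 for actin, 0.06 for GAPDH and 0.07 for the poly-A spike controls, with two-sided exact permutation p of 0.5, 0.8 and 0.9, where the smallest p the design allows is 0.1. By pair, the actin difference was lower in NET each time (2.57 and 2.37, 0.75 and 0.26, 0.36 and 0.17 in ET and NET). An exact sign-flip test of the 3 pairs gave p of 0.25 for actin, the smallest it allows, and 0.75 for GAPDH and the spike controls. A lower actin ratio in NET is therefore not ruled out.

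Alternatives covered no kit term, the replicate block, SPIA arrays alone, the IVT pair alone (no test), leaving out each array, other choices and filters of probe sets, other scalings between arrays, other variance models, array weights, tests over all probe sets and a stricter threshold of 0.01. The script was tested on simulated data for the NET and ET comparison with 19775 genes. It recovered 55.2% of 67 genes shifted by 0.5 log2 units, and 100% of 67 genes each at 1 and 2. Of 206 simulated calls 17 (8.25%) were false, and the 1 shifted list was the 1 list called. The simulated noise was independent between genes and between arrays, with no effect of replicate number. Far fewer genes were shifted than were called in the data, so these rates need not hold for the real arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.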

Results

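Genome-wide expression was measured on 6 microarrays, each hybridised with RNA from LS174T, an established mucin-secreting human colorectal cancer cell line. All cells received 1 µM 4-hydroxytamoxifen for 36 h, which activates proteins fused to ERT2, a tamoxifen-responsive part of the oestrogen receptor. The 3 ET arrays came from cells carrying ERT2 alone and served as the control. The 3 NET arrays came from cells in which ERT2 was joined to NTCF, a TCF fragment used to block transcription by beta-catenin and TCF. Replicate 1 of each group was labelled with a one-cycle IVT kit, and replicates 2 and 3 of each group with SPIA cDNA amplification. Median log2 signal per array lay between 6.14 and 6.21, and the correlation of log2 values between any pair of arrays, across genes, lay between 0.959 and 0.995. The 3′ minus 5′ difference of actin, a measure of RNA quality, was lower in NET in all 3 same-numbered pairs (by 0.20, 0.49 and 0.19).

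The comparison asks which genes differ between NET and ET cells after 36 h of 4-hydroxytamoxifen. As no untreated cells were analysed here, differences between the cells before treatment cannot be told apart from effects of activated NTCF. With a single time point, direct targets of beta-catenin and TCF cannot be told apart from later effects. In NET, 15 of 31 measured genes of absorptive cells and 14 of 23 of mucus-secreting goblet cells rose, by up to 6.89 log2 units for KRT20. Of intestinal stem cell genes 14 of 24 fell, and of known Wnt targets 17 of 33, down to a log2 fold change of −4.27 for ASCL2. Of DNA replication genes 35 of 40 fell and of mitosis genes 35 of 39, by smaller amounts, with medians near −0.58. As lists, all 6 passed with camera's preset correlation and none with an estimated one (adjusted p = 0.226 to 0.422). Of 19775 genes tested with limma, 2971 passed an adjusted p of 0.05, 1267 higher in NET and 1704 lower. A change of at least 1 log2 unit was seen in 554 of them, 391 higher and 163 lower. Larger changes were therefore mostly rises. Falls were more frequent among all calls, but not in every setting: 757 were higher and 690 lower without ET replicate 2, 1429 and 1385 without NET replicate 3, and 482 and 362 without the kit term. The median log2 fold change over all genes was −0.01. With replicate number as a block, 4680 genes passed, of which 1889 were higher and 2791 lower. Fewer passed when the labelling kit was not modelled (844), on SPIA arrays alone (1285), without ET replicate 2 (1447), without ET replicate 3 (1789) or without variance moderation (20). Leaving out replicate 1 of either group gives the SPIA count of 1285, since the remaining IVT array then carries no contrast. Of 91 named genes past the threshold, 33 lost their call without the kit term and 89 without variance moderation. Below, losses without the kit term are given by gene only for some Wnt target, cell cycle and ribosome biogenesis genes.

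The labelling kits were compared directly, because each holds both groups. Among the 1285 genes that passed on SPIA arrays alone, 1276 (99.3%) had the same direction in the IVT pair, against 70.0% of all genes. Across all genes the IVT and SPIA differences had a Pearson r of 0.82, with genes not being independent replicates. Among the 1285, the IVT difference was smaller, with a median ratio to the SPIA difference of 0.769 and a slope of 0.828. Their choice on SPIA arrays favours large SPIA differences. The kit term separated 4852 genes, of which 1124 were higher on the SPIA arrays. It took up 36.5% of the variance summed over all genes, against 46.3% between ET and NET. Genes with large changes weigh most in that sum. The median size of the kit difference over genes was 0.23 log2 units, larger than the 0.15 of the NET minus ET difference. Only replicate 1 was labelled by IVT, so the kit cannot be told apart from a culture or run of replicate 1. That holds for the smaller IVT differences as well.

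**Figure D1:**
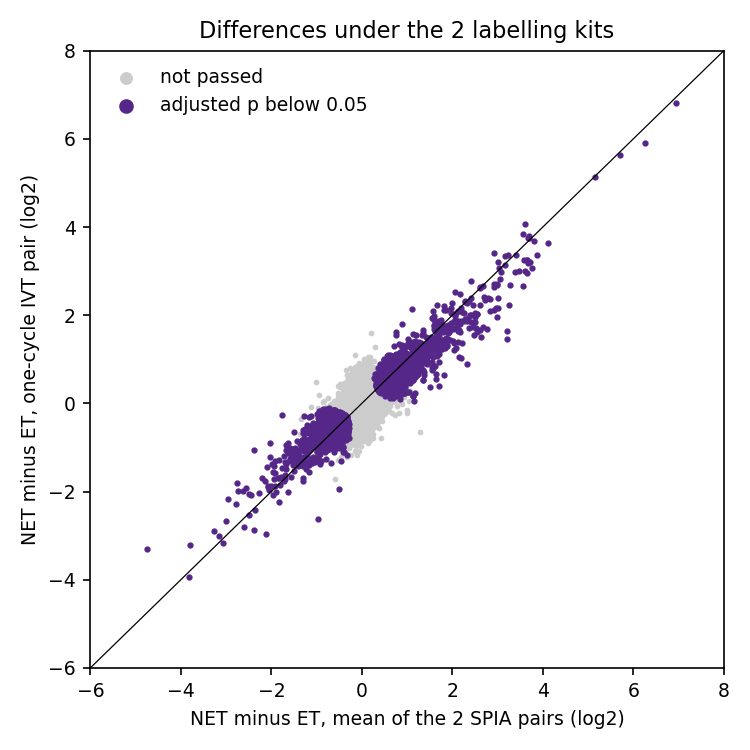
Each point is 1 of 19775 genes. The x axis is the mean NET minus ET difference of the 2 SPIA pairs and the y axis that of the one-cycle IVT pair, both in log2 units; purple points passed adjusted p below 0.05 in the fit to all 6 arrays, and the line marks equal differences. Large differences follow the line's direction (Pearson r across all genes 0.82) but tend to be smaller in the IVT pair, and the furthest point at the upper right is KRT20, with 6.81 in the IVT pair.

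The expression of genes related to the constructs was examined first. TCF7L2, which encodes the TCF factor TCF4, rose by 0.72 log2 units (SE 0.12, adjusted p = 0.00574), from 11.77 ± 0.03 in ET to 12.49 ± 0.17 in NET (SD, n = 3 each). Whether NTCF stems from TCF7L2 and whether its probe sets lie within the NTCF fragment were not analysed here, so the rise checks no label. ESR1, the source of ERT2 in both groups, differed by 0.20 (adjusted p = 0.272), although 1 dim ESR1 probe set without a cross-hybridisation suffix (4.73 in ET) differed by 0.39 (adjusted p = 0.0314 among such probe sets). The other 2 ESR1 probe sets of that kind differed by 0.12 and 0.09 and did not pass. Whether any ESR1 probe set lies within ERT2 was not analysed here either. CTNNB1, which encodes beta-catenin, was at 13.34 ± 0.11 in ET and 13.14 ± 0.15 in NET (SD, n = 3 each). That difference of −0.20 did not pass (adjusted p = 0.328).

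The largest rise was that of KRT20, a keratin of the upper crypt and villus, which went from 6.04 ± 0.50 in ET to 12.93 ± 0.48 in NET (SD, n = 3 each). That is a 119-fold difference of 6.89 log2 units (SE 0.25, adjusted p = 1.22e-05). FABP1, a fatty acid binding protein of enterocytes and liver, rose by 6.14 (SE 0.31). TFF2, a secreted trefoil peptide, rose by 5.69 (SE 0.13), and the membrane protein gene EMP1 by 5.15 (SE 0.18). The adhesion genes CEACAM5, CEACAM7 and CEACAM6 rose by 3.95, 3.77 and 3.71. Also among the 12 largest rises were TFF1 (3.76), the hypoxia-inducible factor EPAS1 (3.73), MALL (3.70), the ileal bile acid transporter SLC10A2 (3.69) and the CDK4/6 inhibitor CDKN2B (3.66). The 12 had adjusted p between 1.56e-06 and 0.000332, and the rule that chose them required a rise in all 3 same-numbered pairs. CDKN2B was at 3.63 in ET, below the absent-sequence controls on all 3 ET arrays (3.72 to 3.88), so the size of its rise is uncertain. The size depended on the probe set in several cases. Averaging all probe sets of a gene gave 2.80 for EMP1, 1.92 for CEACAM5, 2.48 for CEACAM7, 1.40 for EPAS1 and 2.05 for CDKN2B, and probe sets without a cross-hybridisation suffix gave 2.29 for FABP1, all still past the threshold.

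The largest falls were led by ASCL2, a transcription factor of intestinal stem cells. It went from 11.88 ± 0.21 in ET to 7.61 ± 1.08 in NET (SD, n = 3 each), a log2 fold change of −4.27 (SE 0.28, adjusted p = 0.000114). NET replicate 1, labelled by IVT, kept more of it than the SPIA arrays, with a pair difference of −3.31 against −5.01 and −4.50. LRP4, a receptor of the LDL receptor family, fell by 3.86 (SE 0.18) and SMOC2, a secreted stem cell marker, fell by 3.61 (SE 0.20). The adrenergic receptor ADRA2A (−3.14), CYTIP (−3.11) and the prostaglandin D2 receptor PTGDR (−3.11) followed. The transcription factor ETS2 fell by 2.89, the ephrin receptor EPHB3 by 2.70 and ID4 by 2.67. Next came OR51E1 (−2.62), the Wnt inhibitor APCDD1 (−2.54) and RASSF10 (−2.50). Adjusted p lay between 1.22e-05 and 0.00216, and the same rule required a fall in all 3 pairs. The probe set with the largest variance gave −4.70 for PTGDR, averaging probe sets gave −0.94 for ID4 and −1.37 for APCDD1, and probe sets without a cross-hybridisation suffix gave −1.35 for SMOC2, all past the threshold.

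**Figure D2:**
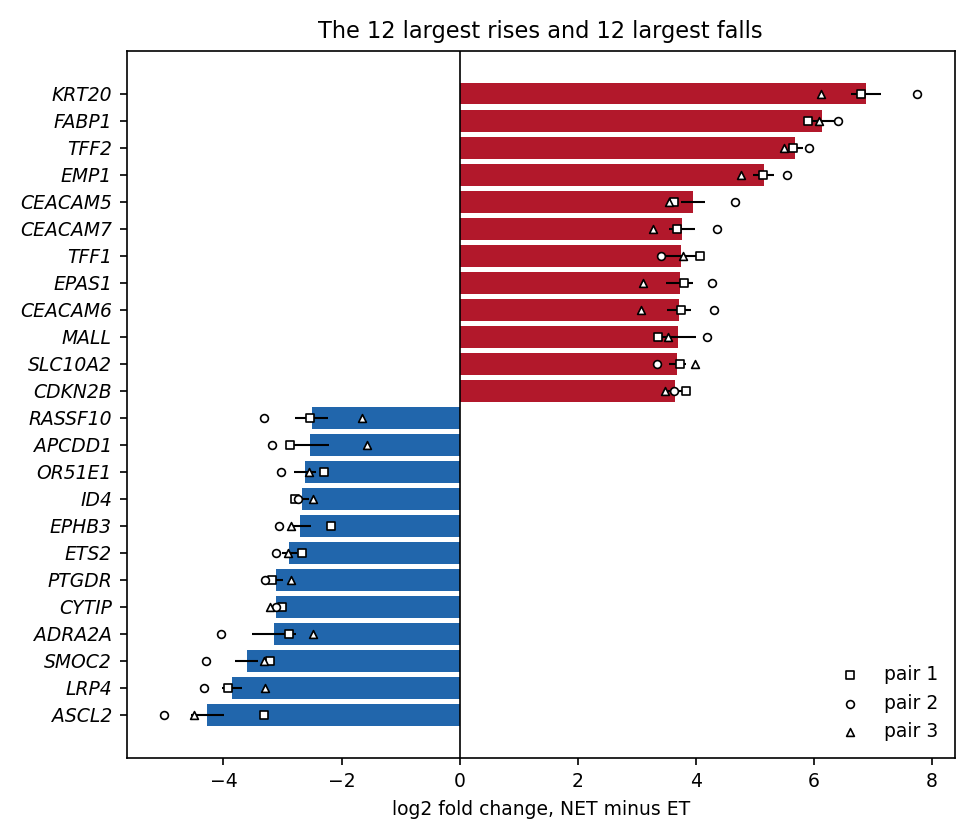
Bars are the fitted log2 fold changes of NET minus ET for the 12 largest rises (red) and 12 largest falls (blue), with lines of ±1 SE. Open symbols are the differences of the 3 same-numbered pairs (square, pair 1, IVT; circle and triangle, pairs 2 and 3, SPIA). The rule that chose these genes required every pair to lie on the same side of 0 as its bar; the bars run from 6.89 for KRT20 to −4.27 for ASCL2.

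Of 33 measured Wnt target genes, 17 fell, 2 rose and 14 did not pass; adjusted over the list alone, 21 fell and 4 rose. AXIN2, a negative regulator of the pathway, fell by 1.33 (SE 0.15, adjusted p = 0.00122). Its call ended when its 4 probe sets were averaged (−0.60, adjusted p = 0.0908). ZNRF3, a ligase that removes Wnt receptors, fell by 2.01 and CD44, an adhesion receptor, by 1.32 (−0.80 over its averaged probe sets). The falls of the stem cell receptor LGR5 (−0.66, adjusted p = 0.0487), MYC (−0.68, adjusted p = 0.0193), NKD1 (−0.88, adjusted p = 0.0322) and SP5 (−0.63, adjusted p = 0.0175) were smaller. The 2 members that rose were DKK1, a secreted Wnt antagonist (3.05), and the urokinase receptor PLAUR (1.79). The list median was −0.59, and limma's camera test with its preset correlation of 0.01 gave an adjusted p of 8.17e-07. With an estimated correlation the adjusted p was 0.422. The list draws on earlier work that includes colorectal cancer lines, so it is not independent evidence of direction.

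The calls of those 4 smaller falls lay near the threshold. All 4 were lost without the kit term (adjusted p = 0.0903 to 0.129), where the differences stayed the same and only the error grew. With replicate number as a block all 91 named calls were kept, these 4 included. LGR5 lost its call without ET replicate 1 or NET replicate 1 (−0.78, adjusted p = 0.129), ET replicate 2 (−0.55, 0.186), ET replicate 3 (−0.71, 0.0917) or NET replicate 3 (−0.44, 0.0540), and also with arrays centred on their medians (0.0543). Choosing the most variable probe set of each gene left LGR5 on the same probe set and moved only its adjusted p (0.0533). A second LGR5 probe set fell by 0.71, with an adjusted p of 0.0126 over all probe sets, against 0.0671 for the first. MYC lost its call without replicate 1 of either group (−0.74, adjusted p = 0.0885) or ET replicate 2 (−0.60, 0.0921). SP5 lost it without replicate 1 of either group (−0.46, adjusted p = 0.111) or ET replicate 3 (−0.65, 0.0515), and NKD1 without ET replicate 2 (−0.62, 0.0813), ET replicate 3 (−0.97, 0.0552) or NET replicate 2 (−0.72, 0.0652). In the IVT pair alone NKD1 differed by −0.31 and SP5 by −0.98, and NKD1 differed by −0.47 over its averaged probe sets.

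Of 24 measured intestinal stem cell genes, 14 fell, none rose and 10 did not pass; adjusted over the list alone, 16 fell. Besides ASCL2, SMOC2 and ZNRF3, the BMP co-receptor RGMB fell by 2.33 (SE 0.13). Its median was −0.93, and camera gave an adjusted p of 4.90e-10, against an adjusted p of 0.226 with an estimated correlation. Several members are shared with the Wnt target list. The list of Paneth cell genes, from the secretory cells at the crypt base, moved in both directions. Of its 12 measured members, the phospholipase PLA2G2A fell by 2.44 and the defensin DEFA6 by 0.85, while CD24 rose by 2.0 and PRSS2 by 0.51. The other 8 did not pass, the counts adjusted over the list alone were also 2 and 2, and the list did not pass (camera adjusted p = 0.546). CD24 and PRSS2 lost their calls without replicate 1 of either group (adjusted p = 0.0609 and 0.193). PRSS2 also lost it without ET replicate 2 (0.10), ET replicate 3 (0.131) or NET replicate 2 (0.0862). Centring the arrays on their medians ended its call too (0.48, adjusted p = 0.0674), and its most variable probe set gave 0.94.

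**Figure D3:**
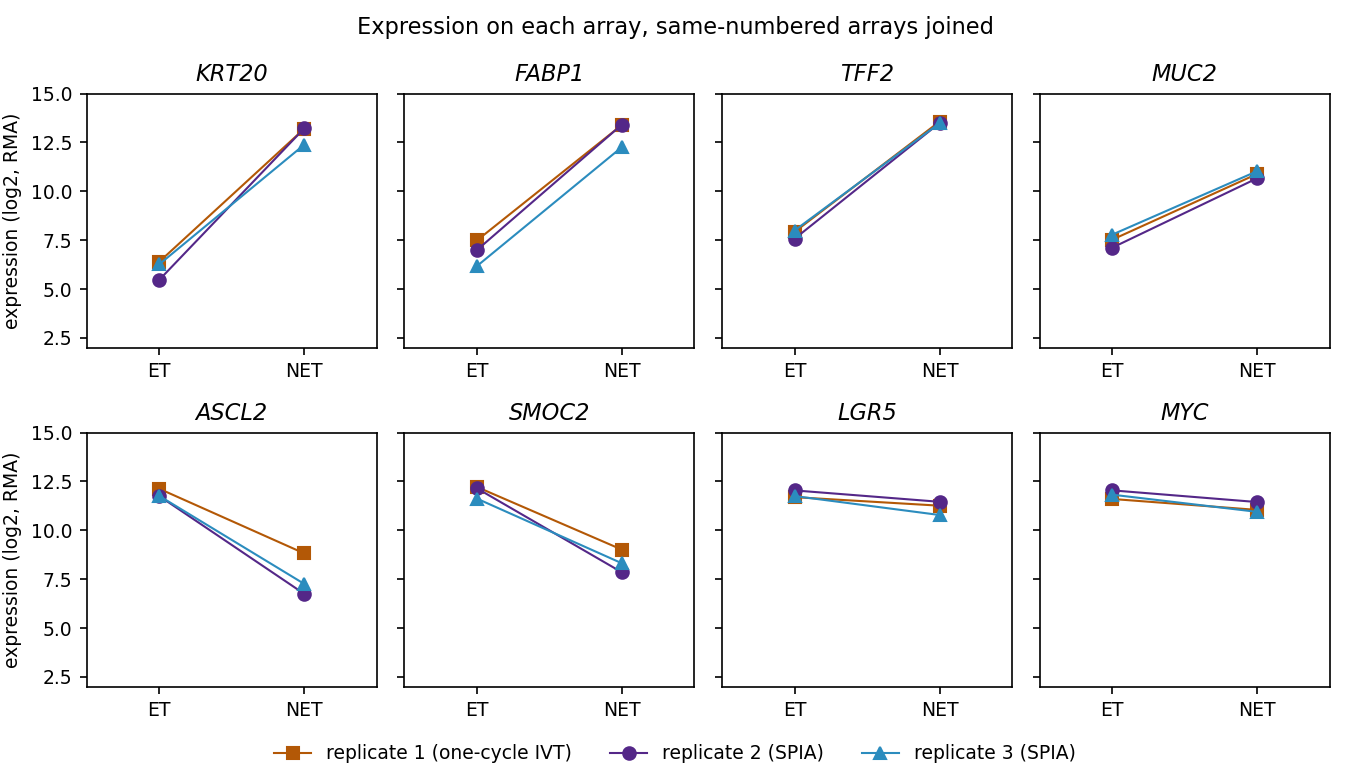
Expression in log2 RMA units (y axis) of 8 genes on each ET and NET array (x axis). Lines join the arrays that share a replicate number, with squares for IVT and circles and triangles for SPIA. KRT20, FABP1, TFF2 and MUC2 are higher in NET in all 3 pairs; the fitted log2 fold change is −4.27 for ASCL2, −3.61 for SMOC2, −0.66 for LGR5 and −0.68 for MYC.

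Goblet cells make the intestinal mucus layer, and 14 of 23 measured goblet cell genes rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone. MUC2, the main gel-forming mucin of the colon, went from 7.47 ± 0.34 in ET to 10.86 ± 0.18 in NET (SD, n = 3 each), a rise of 3.39 (SE 0.18, adjusted p = 5.16e-05). TFF3, the goblet cell trefoil peptide, rose by 2.41 (SE 0.19), and TFF2 and TFF1 were among the largest rises. MUC5AC, a mucin of the stomach surface, rose by 2.68, but its probe sets without a cross-hybridisation suffix gave 0.46 (adjusted p = 0.367). The 1 fall was RETNLB (−0.75). ATOH1, the transcription factor that specifies secretory cells, differed by −0.05 and did not pass. The list median was 0.53, with a camera adjusted p of 4.76e-09, and an adjusted p of 0.226 with an estimated correlation.

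Of 31 measured absorptive cell genes, 15 rose, 2 fell and 14 did not pass; adjusted over the list alone, 16 rose and 2 fell. KRT20, FABP1, EMP1 and CEACAM5 led the list. The transporters SLC5A1 (−0.82) and SLC26A2 (−0.45) fell. Among the 14 that did not pass, SI (0.03), LCT (−0.05), ALPI (0.17), ANPEP (0.14) and FABP2 (0.01) differed little, while DPP4 differed by 1.06. The rise was thus not shared by the whole list. The absorptive list's median was 0.51 (camera adjusted p = 2.53e-10), with an adjusted p of 0.226 when the correlation was estimated. Of 20 measured general epithelial genes 9 rose, none fell and 11 did not pass; adjusted over the list alone, 11 rose and 2 fell. The keratins KRT19 and KRT8 rose by 2.36 and 1.02 and the transcription factor ELF3 by 1.81, and KRT19 by 1.54 over its averaged probe sets. The epithelial list had a median of 0.35 (camera adjusted p = 3.30e-05), with an adjusted p of 0.422 when the correlation was estimated and 0.0578 with fry.

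Enteroendocrine genes, from the hormone-producing cells of the gut, mostly did not pass. Of 20 measured members, ISL1 fell (−0.43, adjusted p = 0.0181) and 19 did not pass; adjusted over the list alone, 1 fell. ISL1 lost its call without replicate 1 of either group (adjusted p = 0.0844), ET replicate 2 (0.0729) or ET replicate 3 (0.0773). PAX6 (−0.29) and SST (−0.32) passed only with the replicate block (adjusted p = 0.0450 and 0.0487). The list's camera adjusted p was 0.815, and its median (0.02) and mean (−0.02) differed in sign.

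Most cell cycle genes measured fell. Of 40 measured DNA replication genes, 35 fell and none rose; adjusted over the list alone, 39 fell. The replication factor RFC4 fell by 0.80 (SE 0.10), the kinase CDC7 by 0.84 (SE 0.11), MCM10 by 0.76 (SE 0.10) and the helicase subunit CDC45 by 0.71 (SE 0.10). The list median was −0.58, with a camera adjusted p of 5.09e-20, and an adjusted p of 0.226 with an estimated correlation. Of 39 mitosis genes, 35 fell and none rose; adjusted over the list alone, 38 fell. The checkpoint kinases TTK and BUB1 fell by 0.70 and 0.75, AURKB by 0.77 and the transcription factor FOXM1 by 0.76. Averaging probe sets gave −0.48 for AURKB and −0.35 for BUB1, which then lost its call (adjusted p = 0.101). Without the kit term RFC4, CDC7, MCM10, TTK and FOXM1 lost their calls (limma adjusted p = 0.0547 to 0.114), while CDC45, BUB1 and AURKB kept theirs. The mitosis list median was −0.58 (camera adjusted p = 7.12e-19), with an adjusted p of 0.276 when the correlation was estimated.

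Of 32 measured genes of ribosome biogenesis, many of them activated by MYC in other settings, 14 fell, none rose and 18 did not pass; adjusted over the list alone, 28 fell. LYAR fell by 0.84, CAD (pyrimidine synthesis) by 0.63, MRTO4 by 0.58 and ODC1 (polyamine synthesis) by 0.56. CAD and MRTO4 lost their calls over averaged probe sets (−0.33, adjusted p = 0.0557, and −0.45, adjusted p = 0.304). MRTO4 also lost it with its most variable probe set (−0.31, adjusted p = 0.738) and on probe sets without a cross-hybridisation suffix (−0.31, adjusted p = 0.755). Without the kit term LYAR and MRTO4 lost their calls (limma adjusted p = 0.345 and 0.0558), while CAD and ODC1 kept theirs. The ribosome biogenesis list's median was −0.39 (camera adjusted p = 2.05e-11), with an adjusted p of 0.422 when the correlation was estimated.

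Among p53 targets and CDK inhibitors, 4 of 22 measured genes rose and 4 fell, with the same counts adjusted over the list alone. CDKN2B (3.66), CDKN1A (the CDK inhibitor p21, 1.13), TP53INP1 (0.65) and TP53I3 (0.52) rose, whereas CDKN1C (−0.75), DDB2 (−0.67), RRM2B (−0.56) and XPC (−0.50) fell. The list did not pass (camera adjusted p = 0.60). Without replicate 1 of either group, the adjusted p was 0.0550 for CDKN1A, 0.0630 for DDB2 and 0.0575 for TP53I3, and without ET replicate 3 it was 0.0573 for TP53I3.

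**Figure D4:**
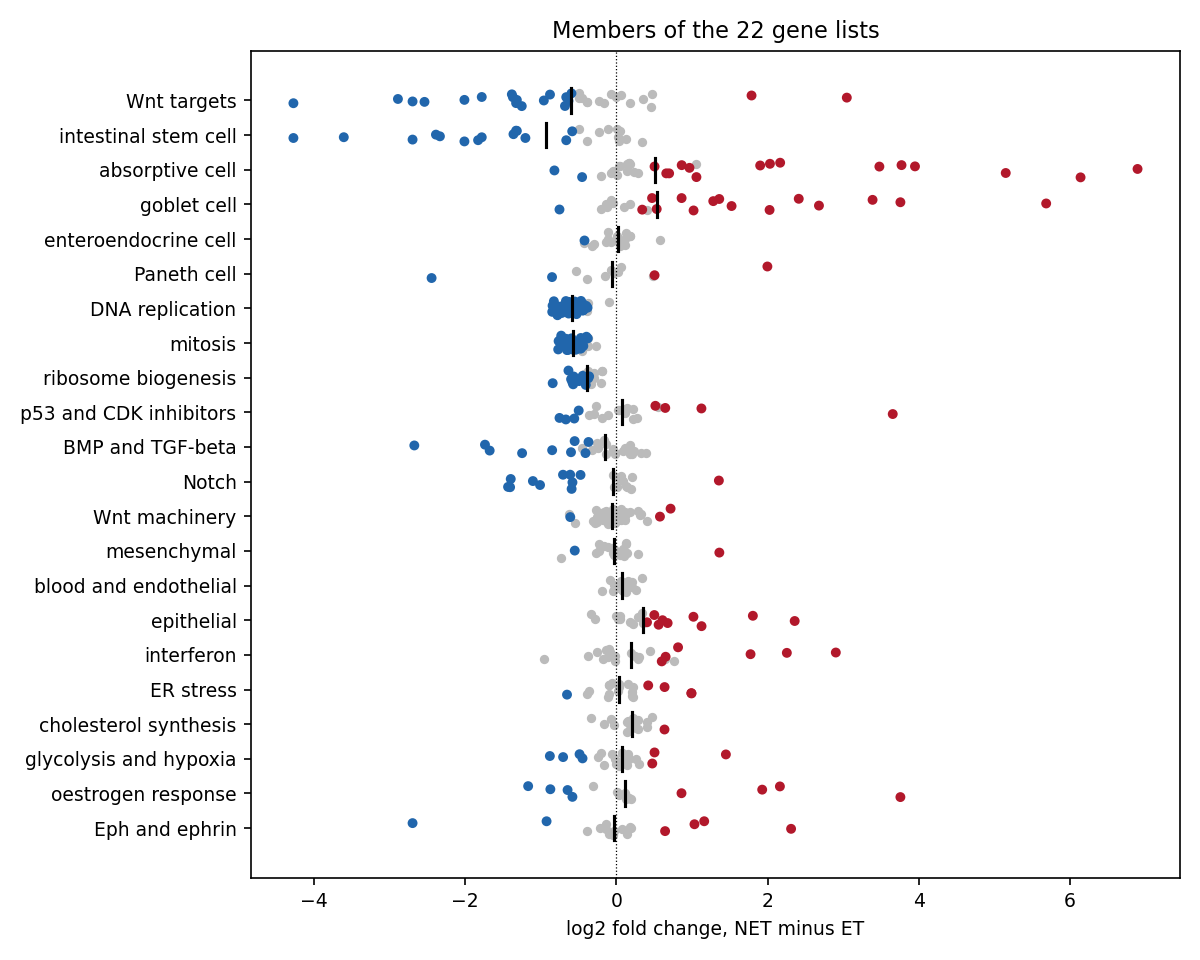
Each point is a measured member of 1 of 22 gene lists, placed by its log2 fold change of NET minus ET (x axis) with random vertical spread within its list (y axis). Red and blue points rose or fell at an adjusted p below 0.05, grey points did not pass, and black bars are list medians. The DNA replication and mitosis lists sit in a narrow band around −0.58, while the absorptive list reaches from −0.82 to 6.89.

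Of 28 measured genes of BMP and TGF-beta signalling, 9 fell, none rose and 19 did not pass; adjusted over the list alone, 10 fell and 1 rose. ID4 fell by 2.67, the signal transducer SMAD9 by 1.74, the ligand BMP4 by 1.68 and ID3 by 1.25, with −0.87 for SMAD9 over its averaged probe sets. This list had a median of −0.15 (camera adjusted p = 0.0116), with an adjusted p of 0.226 when the correlation was estimated and 0.143 on probe sets without a cross-hybridisation suffix. Of 21 genes of Notch signalling, 10 fell, 1 rose and 10 did not pass, with the same counts adjusted over the list alone. The receptor NOTCH1 fell by 1.41, HES6 by 1.43, the glycosyltransferase LFNG by 1.40 and NRARP, a target and inhibitor of the pathway, by 1.01. HES1, a Notch target that represses the secretory fate, rose by 1.36. NOTCH1 and LFNG differed by −0.67 and −0.82 over averaged probe sets. The Notch list median was −0.05 and its mean −0.34 (camera adjusted p = 0.0130), with an adjusted p of 0.290 when the correlation was estimated.

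Components of the Wnt pathway itself mostly did not pass. Of 42 measured, TCF7L2 and the receptor FZD5 (0.58) rose and the receptor FZD3 fell (−0.61), with the same counts adjusted over the list alone and a camera adjusted p of 0.649. FZD2 differed by −0.55 (adjusted p = 0.0588, and 0.0443 with the replicate block). Without replicate 1 of either group, FZD5 and FZD3 lost their calls (adjusted p = 0.0655 and 0.0595), and FZD5 also lost it without ET replicate 2 (0.0501) or on probe sets without a cross-hybridisation suffix (0.0544). In the list of ephrins and their receptors, which position cells along the crypt, 4 of 17 measured members rose and 2 fell. EFNB2 rose by 2.31, EPHA2 by 1.16, EFNA2 by 1.03 and EFNB1 by 0.64, and EPHB3 (−2.70) and EPHA4 (−0.92) fell. EFNA2 lost its call over averaged probe sets (0.29, adjusted p = 0.0644). Adjusted over the list alone, 4 rose and 3 fell, the camera adjusted p was 0.467, and the median (−0.03) and mean (0.06) differed in sign.

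Of 25 measured interferon-stimulated genes, 6 rose, none fell and 19 did not pass; adjusted over the list alone, 7 rose. The exonuclease ISG20 rose by 2.90, OAS1 by 2.26 and OASL by 1.78 (1.04 in the IVT pair), while MX1 (−0.01) and IFIT1 (0.25) did not pass. BST2 rose by 0.65 (0.32 in the IVT pair) but lost its call without ET replicate 2 (adjusted p = 0.0807) or ET replicate 3 (0.0694). This list had a median of 0.20 (camera adjusted p = 0.0182), with an adjusted p of 0.544 when the correlation was estimated. The list did not pass without ET replicate 3 (adjusted p = 0.0961), without NET replicate 2 (0.0917), with array weights (0.0608) or with fry (0.134). Of 17 measured cholesterol synthesis genes, MVD rose (0.63) and none fell, with the same counts adjusted over the list alone. SC5D (0.41), MSMO1 (0.48) and PMVK (0.29) passed only in other settings, among them the replicate block (adjusted p = 0.0168, 0.00923 and 0.0498), and SC5D reversed to −0.04 with another probe set. The cholesterol list median was 0.21 (camera adjusted p = 0.0103), with an adjusted p of 0.607 when the correlation was estimated. That list did not pass without ET replicate 3 (adjusted p = 0.103), without NET replicate 2 (0.116), on probe sets without a cross-hybridisation suffix (0.143) or with fry (0.318). MVD lost its call without replicate 1 of either group (adjusted p = 0.0831), ET replicate 2 (0.0626) or ET replicate 3 (0.0824).

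The remaining lists of stress and hormone responses did not pass as lists, although single members moved. Of 24 measured glycolysis and hypoxia genes, NDRG1 (1.45), SLC2A1 (0.51, and 0.30 in the IVT pair) and ANKRD37 (0.48) rose, and BNIP3 (−0.88), VEGFA (−0.70, or −0.44 over averaged probe sets), EGLN3 (−0.49) and PDK1 (−0.45) fell. Of 20 endoplasmic reticulum stress and amino acid response genes, DNAJB9 (0.99), VLDLR (0.99), HERPUD1 (0.64) and DNAJC3 (0.42) rose and ASNS (−0.65) fell. ASNS lost its call over averaged probe sets (−0.33, adjusted p = 0.0520) and was at 0.00 on probe sets without a cross-hybridisation suffix. Of 17 oestrogen-responsive genes, TFF1 (3.76), the carbonic anhydrase CA12 (2.16), PDZK1 (1.93) and CTSD (0.86) rose, and MYBL1 (−1.17, or −0.36 over averaged probe sets), CELSR2 (−0.87), IGFBP4 (−0.64) and STC2 (−0.58) fell. Adjusted over the list alone, 3 rose and 4 fell for glycolysis and hypoxia, 4 and 2 for endoplasmic reticulum stress, and 4 and 4 for oestrogen response. The camera adjusted p values were 0.60, 0.219 and 0.357, and fry, which tests each list on its own, gave 0.0116 for oestrogen response. Without replicate 1 of either group, VEGFA (adjusted p = 0.0600), VLDLR (0.0742) and ASNS (0.0821) lost their calls. Without ET replicate 2 the same happened to VEGFA (0.0553), SLC2A1 (0.0800), VLDLR (0.0533) and ASNS (0.0603), and without ET replicate 3 to SLC2A1 (0.0673), VLDLR (0.0566) and ASNS (0.0788).

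Markers of cell types outside the epithelium mostly did not pass. Of 16 measured blood and endothelial genes, none passed over all genes or adjusted over the list alone (camera adjusted p = 0.219). The haemoglobin gene HBB differed by 0.33 (adjusted p = 0.134) and the T cell gene CD3D by 0.27 (adjusted p = 0.198). Of 21 mesenchymal genes, LUM rose (1.36, adjusted p = 0.00573), FAP fell (−0.55, adjusted p = 0.0426) and 19 did not pass; adjusted over the list alone, 1 rose and 0 fell. LUM rose from a low level of 4.04 in ET. It was at 0.64 over averaged probe sets, 0.85 in the IVT pair and −0.08 on its probe set without a cross-hybridisation suffix. FAP differed by −0.22 in the IVT pair and lost its call without any 1 of the 6 arrays (adjusted p = 0.0598 to 0.143). TAGLN differed by −0.74 (adjusted p = 0.0604, and 0.0127 with the replicate block). The mesenchymal list's camera adjusted p was 0.963, and its median (−0.03) lay below 0 while camera gave an upward direction.

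DKK1, RETNLB, SLC5A1, SLC26A2, SI, LCT, ALPI, ANPEP, FABP2, DPP4, ATOH1, TP53INP1, CDKN1C, RRM2B, XPC, HES1, EPHA4, EFNB1, MX1, IFIT1, ANKRD37, EGLN3, PDK1, DNAJC3, PDZK1, CTSD, IGFBP4 and STC2 were named after their values were seen, and their values were not computed under the alternative settings.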

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

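The tests of the first 2 patterns weighed here (replicate runs and unequal falls) were chosen after the result was seen, and those of the third (cell cycle lists) and the splits of the arrays before.

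Probe sets without a single gene name lie outside the comparison of genes and also changed. Of 13522 tested with limma over all probe sets, 635 passed, 258 higher and 377 lower in NET, with 471 having no symbol and 164 several. Those 635 are 4.70% of them, against 10.2% of single-gene probe sets. With the replicate block 1096 passed. Of the 10 splits of the arrays into 3 against 3, only 1, the real one, gave as many, and the highest other gave 0. So few splits cannot give a share under 0.05.

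The same holds for the 2971 genes and for the 554 that changed by at least 1 log2 unit, each reached in 1 of 10 splits, with 0 as the highest other. At an unadjusted p of 0.05 limma gave 5430 genes in the real split and at most 1108 in the others. The 12 lists were reached in 3 of 10 splits, with 12 as the highest other, in 2 splits that part the 4 SPIA arrays unevenly. With the kit term, every split other than the real one still carries part of the NET difference. The rest of that difference adds to the residual spread, which works against calls of genes. The 3 other splits that part all 3 same-numbered pairs called 7, 5 and 9 lists and 0 genes. Camera with its preset correlation thus calls lists in splits that call no gene, so passing its threshold does not alone set the real split apart. Since these splits hold part of the NET difference, they do not measure camera's false calls. Its lowest adjusted p was 5.09e-20 in the real split and 1.80e-10 in the lowest other. Among the 12 lists, medians as large in size as the real ones also came up in other splits for Wnt targets (0.62 against −0.59), goblet cell genes (0.60 against 0.53), ribosome biogenesis (0.44 against −0.39), epithelial genes (0.50 against 0.35), interferon (0.34 against 0.20), cholesterol (0.32 against 0.21) and Notch (0.22 against −0.05). In the 3 other splits that part all 3 pairs, the largest sizes were 0.29, 0.29, 0.22, 0.22, 0.14, 0.10 and 0.15 in that order, so Notch was exceeded there too. Each of these splits sets ET replicate 1 against NET replicate 1, so the sizes are not those of lists free of a NET difference.

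Same-numbered ET and NET arrays deviated together, beyond the labelling kit. The poly-A spike controls, which hold no cellular RNA, were 2.58 log2 units higher on replicate 2 than on replicate 3 in NET, and 2.82 higher in ET. Within a number, NET and ET poly-A spikes differed by at most 0.37. These poly-A levels would follow from replicates 2 and 3 having been processed in separate runs that each took in both groups. The spike controls added for hybridisation showed no such shared difference. They were at 10.97 and 10.13 on ET replicates 2 and 3, but at 10.46 on both NET replicates. Whether separate runs made the cellular genes deviate together was not tested. Cultures harvested together by number were not tested and stay open.

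AXIN2, LGR5 and MYC kept far more of their ET level in NET than ASCL2 did. Saturation of bright probe sets is argued against by 7 genes at least as bright in ET as AXIN2 that fell by 2 log2 units or more (ASCL2, EPHB3, ETS2, LRP4, PLA2G2A, RGMB and SMOC2). ASCL2 is itself part of the pattern, so the other genes carry this argument. At least as bright as LGR5 or MYC were 6 such genes, with ASCL2 again included and LRP4 not. AXIN2 kept 39.9% (32.6% to 48.8% at ±2 SE), MYC 62.4% and LGR5 63.2%. Cells that did not respond would keep every gene at their share, but 25 changed genes other than these and ASCL2 kept less than AXIN2 beyond ±2 SE of both. Of these 16 did so on every probe set of the gene, but only 2 of the 16 have several, EPHB3 (15.4%) and RGMB (19.8%). The others, LRP4 (6.90%) among them, have 1 probe set, so for them the check adds nothing. The rest of the 25 have several probe sets and failed it, with up to 115% left on a probe set of ID4 at 2 SE added. These shares come from different probe sets, whose compression of folds was not tested. Other inputs to these genes, slower RNA decay and differing dependence on TCF may account for the difference, and none of them was tested.

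The DNA replication and mitosis lists fell together, with a median of −0.58 over 79 entries. A scaling that lowers all genes of that signal level is argued against by 10000 random lists matched on ET level, whose median was −0.12 and lowest value −0.27. A single pair is argued against as well, since the pair medians were −0.46, −0.68 and −0.61. Slower proliferation of NET cells is a candidate explanation, as is a lower share of cycling cells, and neither was tested since no cell counts were used here.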

How the results depend on the processing

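Among the alternatives, estimated correlation combined with the replicate block, and the symbol families, were chosen after seeing the data. The main counts were 2971 genes, 1267 higher and 1704 lower. Without the kit term 844 genes passed (482 higher, 362 lower), so 57.1% of calls were higher against 42.6%. SPIA arrays alone gave 1285 (639 and 646), a threshold of 0.01 gave 1273 (633 and 640), and no variance moderation gave 20 (10 and 10), 8 of them by at least 1 log2 unit. Leaving out 1 array gave 1285 to 2814 genes, 639 to 1429 higher and 646 to 1531 lower. With the replicate block 4680 passed, all 2971 among them, 2791 of them lower, and unnamed probe sets numbered 1096, against 63 without the kit term. The block gave 7 named genes a call they lacked (PAX6, SST, FZD2, TAGLN, SC5D, MSMO1, PMVK) and changed no other call of a named gene or of a list under the preset correlation. The other normalizations, filters, variance models and array weights kept the counts within 1.5 times.

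With an estimated correlation 0 of 12 lists passed, and 0 with the replicate block added. The medians stay as they were (−0.59 Wnt targets, −0.93 stem cell, 0.51 absorptive, 0.53 goblet, −0.58 DNA replication and −0.58 mitosis) because the alternative changes only the test. The estimate differs in 2 ways, in the correlation itself and in camera's reference distribution, which then has only the 3 residual degrees of freedom. For BMP and TGF-beta (estimated correlation −0.00628) the correlation is not what ended the call. Under all other alternatives these 6 lists kept direction and call. Unmoderated list tests were not run, as camera moderates by itself.

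Of 91 named genes past the threshold, 2 kept it without moderation (TFF2 and NDRG1) and 52 in every other tested setting; 33 lost it without the kit term. Reversed were FN1 (main −0.22, not passing) at 0.062 for averaged probe sets, 0.34 for the most variable and 0.012 without suffixed probe sets, SC5D at −0.040 for the last 2 choices, and LUM at −0.082 and ASNS at 0.0010 without suffixed probe sets. These alternatives read other probe sets of the gene, and the cause was not tested further. No named call reversed in the IVT pair.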

Other observations

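The families and the test of fold sizes were chosen after the data were seen. Genes were grouped by the letters of their symbols into 342 families of at least 8 genes and tested with camera in limma. At an adjusted p of 0.05 with the preset correlation 30 families passed, and 0 passed with an estimated correlation (adjusted p = 0.877), so the counts below describe members. The letters alone decided membership, so a family may hold genes of other kinds. Of 17 symbols of annexins, calcium-dependent membrane-binding proteins, 9 rose and none fell, led by ANXA10 (2.89) and ANXA1 (1.66). Of 18 mucin symbols 8 rose and none fell, with the membrane mucin MUC17 at 3.51. Of 48 keratin symbols 12 rose and 1 fell, and of 11 galectin symbols 5 rose. Of 8 SULT symbols, which cover only part of the sulfotransferases, 4 rose.

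Metallothioneins, small metal-binding proteins, went the other way, with 8 of 10 falling and none rising. MT1G fell by 1.65, MT1F by 1.13, MT1X by 1.12 and MT2A by 1.03. Their sequences are near-identical, so the members are uncertain as separate genes. Of 12 MCM symbols 9 fell, of 26 nucleoporin symbols 10 fell, and of 38 centrosomal CEP symbols 12 fell and 1 rose. Under each of the 3 other scalings between arrays no family named here changed direction; the galectins that rose numbered 3 to 6 and the nucleoporins that fell 7 to 11.

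Fold sizes were compared between the kits on genes chosen because they differed by at least 1 log2 unit in 1 SPIA pair alone. For 812 genes chosen on replicate 2, the median difference in that direction was 1.02 in the IVT pair and 1.11 in the replicate 3 pair. For 568 genes chosen on replicate 3 it was 1.25 in the IVT pair and 1.52 in the replicate 2 pair. With 1 IVT pair this was not tested, and the kit cannot be told apart from replicate 1.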
